A study of Mus musculus with 7 samples.

How the data were processed

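Bulk mcSCRB-seq libraries were made from cortex and hippocampus of 24 mice, with 47 wells spread over 7 library pools. The deposited table holds raw whole-number counts per gene symbol and well, per the file headers and the values themselves. Per the submitters' processing notes, bcl2fastq 2.17 and STAR 2.5.3a were among the tools the authors used. The genome build, the annotation, the program that counted reads and whether molecular identifiers were collapsed are not given in the sources used here, so no coordinates are printed. The assay tags 3' ends, so a count does not scale with transcript length. Of 20859 genes listed, 97.85% (20411) had a symbol in mouse annotation M21.

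Each deposited sample is a pool of several mice whose label names IgG, PBS and CD38 together. The mouse, region, genotype and injection of each well were therefore taken from the deposited sample sheet, matched by well. For 1 mouse of pool 8 the sheet gave CD38 and the well name IgG, and its 2 wells were left out of every comparison between groups, entering only that of hippocampus with cortex, where each mouse is its own block. Pairs of replicates were compared by a chi-square test of their counts, and the lowest ratio to the degrees of freedom was 2.738, so none was counted as a repeat of another. The replicate was the mouse, and both regions came from the same mice. Xist was counted in all 47 wells (at least 54 counts), so sex was not used as a covariate.

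Choices of test, samples, covariates, gene lists and named genes were made before the data were examined. Counts of each region were fitted with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood test, TMM factors, filterByExpr with a minimum count of 10 and a total of 15), with the pool as an additive factor and all groups in 1 fit. The main tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p of 0.05. The mean of both regions and the difference between regions were fitted with limma 3.58.1 (voom, with the mouse as a correlated block), and hippocampus against cortex with edgeR and the mouse as a block. The comparisons of FAD IgG with WT and of FAD CD38 with WT share the WT mice, and no overlap between their calls is given.

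Of 44 gene lists written beforehand, 40 were tested in cortex and 39 in hippocampus, those with at least 3 tested genes, by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry. Camera asks whether the genes of a list differ from other genes, and fry whether they move 1 way on balance. For 12 lists the level per mouse was the mean log2 CPM with a prior count of 2, compared by two-sided exact permutation tests adjusted over the 12 lists. Named genes were, per comparison, the 10 of smallest adjusted p in each direction, up to 4 members of smallest p in each list called, and a fixed set of check genes, and some of these genes are not reported here. Where fewer than 5 genes passed, the 10 of smallest p were given as values. Il1b, 1 of the check genes, did not pass the filter and was not tested.

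The code was tested on simulated counts drawn for the real genes and library sizes. For FAD IgG against WT 35.8%, 82.1% and 100% of genes changed by 1.5, 2 and 4-fold were recovered in cortex over 12968 genes, and 16.4%, 73.1% and 98.5% in hippocampus over 12728. For FAD CD38 against FAD IgG these were 26.9%, 73.1% and 100%, and 20.9%, 71.6% and 98.5%. For FAD CD38 against WT they were 29.9%, 83.6% and 97%, and 19.4%, 74.6% and 98.5%. For the fits of both regions, log2 values with normal noise of 1 SD per gene, the same in every well, were simulated in place of counts. Over the mean of both regions the shares recovered were 58.2%, 91% and 100% for FAD CD38 against FAD IgG over 12915 genes. For its difference between regions they were 20.9%, 74.6% and 92.4%. For hippocampus against cortex, again in simulated counts, they were 94%, 100% and 100% over 12434 genes. A simulated list of 25 genes changed by 1.2-fold was called in every comparison of groups, and 0 of 30 unchanged lists were. The genes of these lists were picked at random and simulated independently. How often camera calls unchanged lists of correlated genes, such as the striatal markers (estimated correlation 0.74 in cortex), is therefore not shown. The square root of the common dispersion was 0.197 in cortex and 0.23 in hippocampus, and totals of 1270918 to 5101368 counts per well leave genes of a few CPM with few counts.

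Alternatives set beforehand were DESeq2 1.42.0 (median-of-ratios size factors), RLE factors, no filter on low counts, a mean of at least 10 counts per well, the pool left out of the model, only the 2 groups compared, mitochondrial genes left out, voom with sample quality weights, and each pool left out in turn. For levels a prior count of 0.5 and levels after removing the pool were tried, and for hippocampus against cortex a fit without the mouse block. Chosen after seeing the data were the mouse of conflicting labels counted as IgG or as CD38, the 8 wells with a ribosomal RNA share over 1.5 times their region's median left out, that share as a covariate, and for levels WT replicate 9 left out in hippocampus. The ribosomal RNA share sums genes annotated as ribosomal or as mitochondrial ribosomal RNA, so it can overlap the mitochondrial share of counts. Wells of high share were, in cortex, FAD CD38 replicate 7 (9.37%), FAD IgG replicates 4 (13.4%) and 5 (13.2%) and WT replicate 9 (8.12%). In hippocampus they were FAD CD38 replicate 4 (17.2%), FAD IgG replicates 4 (15.3%) and 7 (10.3%) and WT replicate 9 (23.7%). Figures were drawn with matplotlib 3.10.9.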

Results

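Gene expression was measured in the cortex and hippocampus of mice carrying familial Alzheimer's disease transgenes (FAD) and of wild-type mice (WT), to ask what targeting CD38 changed in this model. CD38 is a surface enzyme that consumes NAD. The assay, mcSCRB-seq, tags the 3' ends of transcripts with a barcode per well so that many samples are sequenced as 1 pool. The 7 pools held 47 wells from 24 mice. In cortex there were 7 FAD mice given a control IgG, 7 FAD mice of the CD38 group and 9 WT mice given PBS, and in hippocampus 7, 7 and 8. The sample sheet called 1 further mouse CD38 and its well name called it IgG, so it entered no comparison between groups. Genotype and injection differ together against WT, since the WT mice had PBS and the FAD mice an antibody.

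Total counts per well ran from 1270918 to 5101368. The medians in cortex were 3090289 for FAD IgG, 2890018 for FAD CD38 and 3509152 for WT, and in hippocampus 3317817, 2641237 and 3275734.5. The ribosomal RNA share, mitochondrial ribosomal RNA included, was 6.74% ± 4.53 (SD, n = 7) in cortex of FAD IgG mice, 5.59% ± 2.2 (n = 7) in FAD CD38 and 6.19% ± 1.43 (n = 9) in WT. In hippocampus it was 7.10% ± 4.27 (n = 7), 7.08% ± 4.63 (n = 7) and 7.21% ± 6.71 (n = 8). None of 18 tests of totals and RNA shares between groups passed. The lowest two-sided exact permutation p was 0.041 (adjusted p = 0.577), for the total counts in hippocampus of FAD CD38 against WT.

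Tissue identity was compared first. Among 23 mice with both regions, the mouse of conflicting labels included, 2988 genes were higher in hippocampus and 2820 higher in cortex of 12434 tested, with the mouse as a block. Of the hippocampal markers, 12 of 14 were higher in hippocampus (median log2 difference 2.67), among them C1ql2 of the dentate gyrus (5.07), Spink8 of pyramidal cells (4.52) and Cabp7 (3.45). Of 22 cortical markers, 17 were higher in cortex and 5 in hippocampus (median -1.34), with Rspo1 at -3.25 and Myl4 at -3.22. Of 9 striatal markers 8 were higher in cortex (median -1.98), with Ppp1r1b at -2.46. The choroid plexus list had 2 members, of which 1 was higher on either side, and Ttr, the transthyretin of choroid plexus, was higher in hippocampus (1.61).

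In cortex, FAD IgG mice carried far more transcripts of microglia and of reactive astrocytes than WT mice. Cst7, a cystatin of plaque-associated microglia, rose from 1.84 ± 0.921 CPM (counts scaled to the library total, SD, n = 9) to 183 ± 27.6 (n = 7), a log2 fold change of 6.79 ± 0.25 (SE, adjusted p = 1.67e-14). Gfap, the astrocyte intermediate filament, rose from 27.8 ± 5.77 to 274 ± 97.0 CPM (3.39 ± 0.18, adjusted p = 7.15e-12), and Trem2, a microglial lipid receptor, rose by 2.96 ± 0.18 (adjusted p = 1.04e-10). Fewer genes fell, among them Npas4, an activity-induced transcription factor (-1.49 ± 0.24, adjusted p = 0.000133), and Serpini1, the neuroserpin gene (-0.51 ± 0.09, adjusted p = 0.000638). By edgeR's quasi-likelihood test 433 genes rose and 69 fell of 12968 tested. The number that fell was 15 without pool 5, 41 without pool 6, 210 without pool 7, 44 without pool 8, 16 without pool 9 and 24 without pool 11, and 17 without wells of high ribosomal RNA share, a setting chosen after seeing the data.

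Thy1 and App rose too, and whether their counts include transcripts of the transgenes was not tested. Thy1, the gene of a neuronal surface glycoprotein, went from 165 ± 12.8 to 774 ± 188 CPM (2.21 ± 0.13, adjusted p = 1.53e-11). App, the amyloid precursor gene, rose by 0.54 ± 0.13 (adjusted p = 0.014), a call lost in 4 alternatives, among them without pool 9 and without pool 11. Cd38 itself was low, at 3.90 ± 1.40 CPM in FAD IgG against 2.43 ± 1.16 in WT, and passed no test (adjusted p = 0.405). Clec7a and Itgax, markers of plaque-associated microglia, had 4 and 3 counts over all WT cortices, so they are given only as levels: 15.3 ± 7.06 CPM in FAD IgG against 0.178 in WT for Clec7a, and 8.92 ± 5.35 against 0.096 for Itgax.

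Of the disease-associated microglia list in cortex 32 of 34 members rose (33 when adjusted over the list alone), with a median log2 fold change of 2.46. Its members include Lyz2, a lysozyme (2.96), and Ccl6, a chemokine that also stood among the strongest single genes (3.78). Homeostatic microglia genes rose in 12 of 18 cases (14 adjusted over the list alone, median 0.96), including Cx3cr1, the fractalkine receptor (0.93), and Siglech (1.24). Reactive astrocyte genes rose in 15 of 21 (18 adjusted over the list alone), among them Serpina3n, a protease inhibitor (3.69), and Vim, the vimentin gene (2.16), while the homeostatic astrocyte list was not called (1 of 20 rose, also 1 adjusted over the list alone, adjusted p = 0.739). Complement genes rose in 10 of 12 (11, with 1 lower, adjusted over the list alone), among them C4b (3.43), C1qc (2.01) and C1qb (1.86). Lysosomal genes rose in 18 of 28 (19 adjusted over the list alone), with Cd68 at 2.90, Ctss at 2.05 and Ctsz at 1.68.

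Antigen presentation and interferon genes moved with them in cortex. Interferon response genes rose in 20 of 23 cases (22 adjusted over the list alone, median 1.27), among them Ifit3 (1.64) and Ifitm3 (1.17). MHC class I genes rose in 9 of 12 (12 adjusted over the list alone), with B2m at 1.56 and H2-K1 at 1.39, and MHC class II genes in 7 of 7 (7 adjusted over the list alone), with Cd74 at 2.07. Reads of H2 genes can be shared between near-identical copies, so the single H2 values are uncertain. The list of oligodendrocyte genes induced in disease rose in 8 of 11 (8 adjusted over the list alone, median 1.39), with the protease gene Klk6 at 2.11. In the IL-1 and IL-17 list 4 of 14 rose (5 adjusted over the list alone), led by the inflammasome adaptor Pycard (1.63) and the TNF receptor Tnfrsf1a (1.12). These lists, like those of microglia, astrocytes, complement and lysosome, kept their call in camera with an estimated correlation, the weakest adjusted p being 0.006 for the lysosome.

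Genes of the nuclear respiratory chain were lower in FAD IgG cortex as a list, with 73 of 75 below 0 and a median of -0.30, although only 5 fell singly (31 adjusted over the list alone). This call was lost in camera with an estimated correlation (adjusted p = 0.198) and kept by fry (adjusted p = 0.0319). They included Ndufb6 (-0.45), Ndufc2 (-0.39) and Ndufv2 (-0.43), all of complex I. Their single calls were lost in 4, 5 and 8 of the alternatives tried, all 3 of them without pool 5 or pool 9, and that of Ndufv2 also without any 1 of pools 6, 8, 10 and 11 and that of Ndufc2 without pool 11. The call of the mitochondrially encoded genes was also lost with an estimated correlation (adjusted p = 0.189) and kept by fry (adjusted p = 0.0397). Of these genes 0 of 11 fell singly by edgeR (7 adjusted over the list alone, median -0.41). The mitochondrial share of counts was 11.9% in FAD IgG, 11.2% in FAD CD38 and 13.1% in WT. Striatal markers were lower in 12 of 12 cases, with 0 called singly (7 adjusted over the list alone, median -0.80, adjusted p = 0.151 with an estimated correlation). Immediate early genes had a median of -0.36, with 1 of 21 falling (4 adjusted over the list alone, adjusted p = 0.151 with an estimated correlation). The list calls for tricarboxylic acid cycle (0 of 20 changed, median -0.12, adjusted p = 0.553), fatty acid oxidation (0 of 16, median -0.12, 0.55), cholesterol synthesis (2 of 20 rose, also 2 adjusted over the list alone, median 0.14, 0.266) and oligodendrocyte genes (2 of 20 rose, also 2 adjusted over the list alone, median 0.08, 0.588) were likewise lost, the last value of each being the adjusted p with an estimated correlation. NAD metabolism genes were not called as a list (adjusted p = 0.656), with 2 of 25 higher (2 adjusted over the list alone).

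Further genes that fell in FAD IgG cortex were Apln, a peptide hormone (-0.84), Btbd17 (-0.67), the long noncoding RNA Pantr1 (-0.70, lost in 1 alternative), the glycine receptor subunit Glrb (-0.47, lost in 2), the GABA receptor subunit Gabra5 (-0.54) and Mrps36 (-0.52). By camera with the preset correlation 13 of 40 lists were higher and 6 lower in FAD IgG cortex, and 11 kept their call with an estimated correlation. The disease-associated microglia level per mouse was 6.08 ± 0.24 (mean log2 CPM, SD, n = 7) against 3.83 ± 0.11 (n = 9), above the WT mean in 7 of 7 mice, with a two-sided exact permutation p of 8.74e-05, the smallest this design can give (adjusted p = 0.000131). Within the 6 pools that held both groups it was higher in 6 of 6, by 2.03 to 2.66. DESeq2 split its calls into 453 higher and 156 lower, voom with sample quality weights into 510 and 296, and a fit of only the 2 groups compared into 346 and 26. Among alternatives chosen after seeing the data, the ribosomal RNA share as a covariate gave 763 and 389 and the mouse of conflicting labels counted as IgG 461 and 126.

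**Figure D1:**
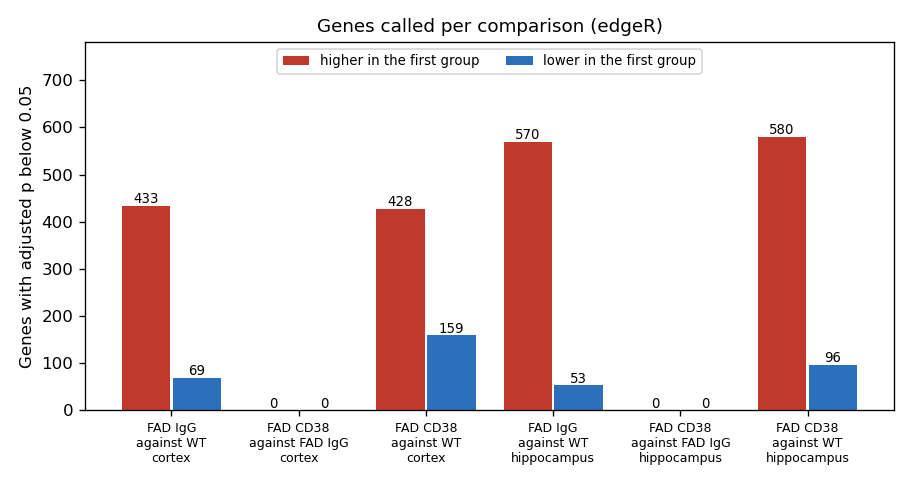
Bars give the number of genes called higher or lower at an adjusted p of 0.05 (y axis, edgeR) for each comparison of groups in cortex and hippocampus. FAD IgG against WT stands at 433 higher and 69 lower in cortex and 570 and 53 in hippocampus, while FAD CD38 against FAD IgG stands at 0 in both.

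In hippocampus the same kinds of transcripts rose in FAD IgG mice. Cst7 rose from 1.93 ± 1.21 CPM (SD, n = 8) to 168 ± 32.1 (n = 7), a log2 fold change of 6.55 ± 0.30 (SE, adjusted p = 8.4e-11). Gfap rose by 2.74 ± 0.14 (adjusted p = 1.91e-10), Tyrobp, the signalling partner of Trem2, by 2.72 ± 0.14 (adjusted p = 1.4e-10) and Trem2 by 3.03 ± 0.21 (adjusted p = 4.6e-09). Thy1 went from 162 ± 8.64 to 934 ± 106 CPM (2.52 ± 0.14, adjusted p = 3.43e-10) and App rose by 0.76 ± 0.17 (adjusted p = 0.00962, lost without pool 9). The genes that fell included Spink8 of pyramidal cells (-1.08 ± 0.20, adjusted p = 0.00121) and Crhbp, a binding protein of corticotropin releasing hormone found in interneurons (-0.70 ± 0.13, adjusted p = 0.00109). In all 570 rose and 53 fell of 12728 tested. Without pools 5 to 11 in turn the number that fell was 21, 17, 87, 142, 22, 9 and 23.

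In hippocampus the disease-associated microglia list rose in 33 of 34 members (33 adjusted over the list alone, median 2.67) and homeostatic microglia genes in 13 of 18 (14 adjusted over the list alone, median 1.10), with Csf1r at 1.46. Reactive astrocyte genes rose in 19 of 23 (22 adjusted over the list alone, median 1.79) and complement genes in 12 of 13 (12 adjusted over the list alone), with C1qa at 2.63 and C4b at 2.84. Interferon response genes rose in 23 of 23 (23 adjusted over the list alone, median 1.75), with Ifi27l2a at 3.55, Usp18 at 3.01 and Bst2 at 2.02. MHC class I genes rose in 10 of 11 (11 adjusted over the list alone) and class II genes in 6 of 7 (7 adjusted over the list alone, median 3.51), with Cd74, the invariant chain, at 4.24. Lysosomal genes rose in 18 of 29 (20 adjusted over the list alone), disease-induced oligodendrocyte genes in 8 of 11 (9 adjusted over the list alone) and the IL-1 and IL-17 list in 6 of 14 (7 adjusted over the list alone), with Lcn2, a siderophore-binding lipocalin, at 3.27.

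Inhibitory neuron markers were lower as a list in FAD IgG hippocampus, with a median of -0.31 and an adjusted p of 0.00373 with an estimated correlation, although 0 of 17 were called singly (2 lower adjusted over the list alone). The neuropeptide genes Cck (-0.42, adjusted p = 0.0638), Cort (-0.80, 0.0687) and Sst (-0.45, 0.186) were its leading members. The remaining calls were lost with an estimated correlation. Antioxidant genes rose in 4 of 19 (5 adjusted over the list alone, adjusted p = 0.15 with an estimated correlation), among them Prdx6 (0.92) and Nfe2l2, a regulator of the oxidative stress response (1.12). Homeostatic astrocyte genes rose in 5 of 20 (5 adjusted over the list alone, adjusted p = 0.179 with an estimated correlation), with the water channel Aqp4 at 1.57. Immediate early genes fell in 2 of 21 (3 adjusted over the list alone, median -0.30, adjusted p = 0.295 with an estimated correlation), Nr4a1 at -0.74 and Junb at -0.63, single calls lost in 2 and 8 alternatives, both of them without pool 6 and Junb also without pool 5, 9, 10 or 11. The nuclear respiratory chain list was lower in 72 of 75 members with a median of -0.19, with 0 called singly (0 adjusted over the list alone, adjusted p = 0.497 with an estimated correlation).

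For tricarboxylic acid cycle genes in FAD IgG hippocampus the median was -0.26 (adjusted p = 0.309 with an estimated correlation), for cholesterol synthesis 0.34 (1 of 21 rose, 5 adjusted over the list alone, adjusted p = 0.0706 with an estimated correlation) and for oligodendrocyte genes 0.29 with Cldn11 rising by 1.07 (3 of 20, 4 adjusted over the list alone, adjusted p = 0.309 with an estimated correlation). The oligodendrocyte precursor list had 0 of 14 called (median 0.34, adjusted p = 0.287 with an estimated correlation). Hippocampal markers split into 1 higher and 2 lower of 17 (1 and 3 adjusted over the list alone, median -0.15, adjusted p = 0.295 with an estimated correlation). Other genes that fell were Ppp1r3g (-1.0), Dusp5, a phosphatase of MAP kinases (-0.79), Apln (-0.78) and Igfbp4 (-0.53), of which Ppp1r3g lost its call without pool 10, Apln without pool 7 and Igfbp4 without pool 6 or pool 11.

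Of 39 lists tested in FAD IgG hippocampus 16 were higher and 5 lower, and 12 kept their call with an estimated correlation. The disease-associated microglia level was 6.20 ± 0.18 (n = 7) against 3.79 ± 0.18 (n = 8), higher in 7 of 7 mice than the WT mean and in 6 of 6 pools, by 2.05 to 2.84, with an exact permutation p of 0.000155, the smallest this design can give (adjusted p = 0.000232). The WT hippocampus of replicate 9 had a ribosomal RNA share of 23.7%. DESeq2 split its calls into 634 higher and 149 lower, voom with sample quality weights into 1194 and 734, and no filter on low counts gave 682 and 31. Among alternatives chosen after seeing the data, leaving out wells of high ribosomal RNA share gave 739 and 382 and the share as a covariate 855 and 263, and with the mouse of conflicting labels counted as IgG 105 were lower.

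Over the mean of both regions 765 genes rose and 218 fell of 12915 in FAD IgG mice, voom with sample quality weights gave 1174 and 886, and the pool left out of the model 752 and 136. Of 427 genes higher in cortex and 552 higher in hippocampus among the 12467 tested in both, 367 were shared, where independent lists would share 18.9. Of 66 and 53 lower genes 4 were shared, against 0.281. The same mice supplied both regions, so these lists are not independent samples.

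The size of the FAD IgG effect differed between regions for 30 genes, 27 of them with the higher log2 change in hippocampus and 3 in cortex (limma voom with the mouse as a correlated block). They included Endou (difference 2.10, adjusted p = 1.47e-06), Klk6 (1.46, adjusted p = 0.000338), Cd74 (2.51, adjusted p = 0.00097) and Cd52 (1.15, adjusted p = 0.00256). Voom with sample quality weights gave 304 and 169 in place of 27 and 3, and leaving out wells of high ribosomal RNA share, chosen after seeing the data, 11 in all.

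The CD38 group was then set against the IgG group of the same genotype. In cortex no gene passed the test: edgeR called 0 of 12968, and DESeq2 and voom with sample quality weights called 0. By edgeR 195 genes had an unadjusted p under 0.05, where evenly spread p-values would give 648.4. Other splits of the same mice, drawn across pools, gave a median of 456. The smallest p belonged to Ccnt1, a cyclin of the elongation factor P-TEFb (log2 fold change 0.54 ± 0.15, adjusted p = 1), and S1pr5, a sphingosine phosphate receptor of oligodendrocytes (-0.55 ± 0.15, adjusted p = 1). Others with adjusted p = 1 were Art3 (-0.83), Adat2 (-0.86), Cela1 (-0.64), Fkbp5, a glucocorticoid-induced chaperone (0.60), Jam2 (-0.50), Klk6 (-0.47), Zfp949 (-0.51) and Cdk5r1 (0.42). The markers of the FAD effect did not pass either, with Cst7 at -0.09 ± 0.18, Trem2 at -0.08 ± 0.18, Gfap at -0.24 ± 0.17 and Thy1 at 0.15 ± 0.13. Cd38 stood at -0.12 ± 0.33, with 3.57 ± 1.32 CPM (SD, n = 7) in the CD38 group and 3.90 ± 1.40 (n = 7) in the IgG group.

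In hippocampus edgeR also called 0 of 12728 genes between FAD CD38 and FAD IgG, and DESeq2 and voom with sample quality weights called 0. By edgeR 197 genes had an unadjusted p under 0.05, where evenly spread p-values would give 636.4 and other splits of the mice gave a median of 359. Ddo, a D-aspartate oxidase (-0.71 ± 0.20), and Pde7a, a cyclic AMP phosphodiesterase (0.54 ± 0.15), had the smallest p, each with an adjusted p of 1. Next came Csgalnact2 (-0.78), Depp1 (1.36), Cav1, the caveolin of endothelial caveolae (-0.58), Zrsr1 (1.31), Tmtc2 (1.07), Aldh1a1, a retinoic acid producing enzyme (-0.74), Trp53 (-0.51) and Mfsd13a (0.82). Cst7 stood at 0.07 ± 0.22, Trem2 at 0.11 ± 0.19, Gfap at -0.21 ± 0.13, Thy1 at 0.04 ± 0.13 and Cd38 at -0.06 ± 0.23. The 95% interval of the log2 change lay within 1 unit of 0 for 95.6% of genes in cortex and 93.2% in hippocampus. In simulated counts for this comparison, over the same genes, 73.1% of genes changed by 2-fold were recovered in cortex and 71.6% in hippocampus, against 26.9% and 20.9% at 1.5-fold. Simulated genes were drawn independently, so genes that move together between mice are not covered by these shares.

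No member of any list was called singly between FAD CD38 and FAD IgG in either region. Camera with the preset correlation called 17 of 40 lists in cortex, 4 higher and 13 lower, and 9 of 39 in hippocampus, 3 higher and 6 lower, and 0 in either region with an estimated correlation or with fry. The interferon response list was lower in both, with 20 of 23 members below 0 in cortex (median -0.20, adjusted p = 0.428 with an estimated correlation) and 23 of 23 in hippocampus (median -0.28, adjusted p = 0.517 with an estimated correlation). Its members included Ifit3 (-0.35 in cortex and -0.40 in hippocampus) and the guanylate-binding protein gene Gbp2 in hippocampus (-0.77). Per mouse the interferon level did not differ by a two-sided exact permutation test, with p = 0.149 (adjusted p = 0.773) in cortex and p = 0.15 (adjusted p = 0.922) in hippocampus. It was lower in 5 of 6 pools in each region.

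Lists lower in FAD CD38 than in FAD IgG cortex by the preset correlation alone were oligodendrocyte (median -0.16, adjusted p = 0.428 with an estimated correlation), homeostatic astrocyte (-0.14, 0.428), reactive astrocyte (-0.12, 0.428), homeostatic microglia (-0.11, 0.428), endothelium (-0.09, 0.428), meningeal fibroblast (-0.24, 0.428) and disease-induced oligodendrocyte genes (-0.11, 0.428), then disease-associated microglia (-0.09, 0.551), complement (-0.13, 0.461), MHC class I (-0.10, 0.481), fatty acid oxidation (-0.12, 0.482) and lysosome (-0.05, 0.592). Those higher were immediate early (0.13, 0.461), glycolysis (0.07, 0.505), synaptic vesicle (0.07, 0.482) and blood genes (0.75, 0.461), the last including haemoglobin genes whose reads can be shared between copies. Without pool 5 the number of lists called in cortex was 7 and without pool 7 it was 8, and with the pool left out of the model 11.

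In hippocampus the lists called beside the interferon response were oligodendrocyte genes, lower in 20 of 20 members (median -0.17, adjusted p = 0.517 with an estimated correlation), reactive astrocyte (-0.18, 0.517), ependyma (-0.24, 0.517), homeostatic astrocyte (-0.08, 0.524) and MHC class I (-0.14, 0.772). Higher were immediate early (0.30, 0.517), blood (0.79, 0.532) and nuclear respiratory chain genes, the last in 63 of 75 members (0.09, 0.807), a direction that turned when wells of high ribosomal RNA share were left out after seeing the data (adjusted p = 0.0122 with the preset correlation). Over the mean of both regions limma voom with the mouse as a correlated block called 0 genes, and voom with sample quality weights called 0 (665 at an unadjusted p under 0.05). Without the weights 233 genes had an unadjusted p under 0.05, where evenly spread p-values would give 645.8 and other splits of the mice gave a median of 393. Without wells of high ribosomal RNA share, a setting chosen after seeing the data, 1334 genes had an unadjusted p under 0.05 and 0 were called. Klk6 (-0.55), Aldh1a1 (-0.70) and Zrsr1 (1.12) led by p, each with an adjusted p of 1. In simulated log2 values for this mean over 12915 genes 58.2% of genes changed by 1.5-fold were recovered and 91% of those changed by 2-fold. These values had the same noise in every well and were not counts, so wells of differing quality are not covered. The effect differed between regions for 0 genes by limma voom (289 at an unadjusted p under 0.05) and for 0 with sample quality weights (582).

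**Figure D2:**
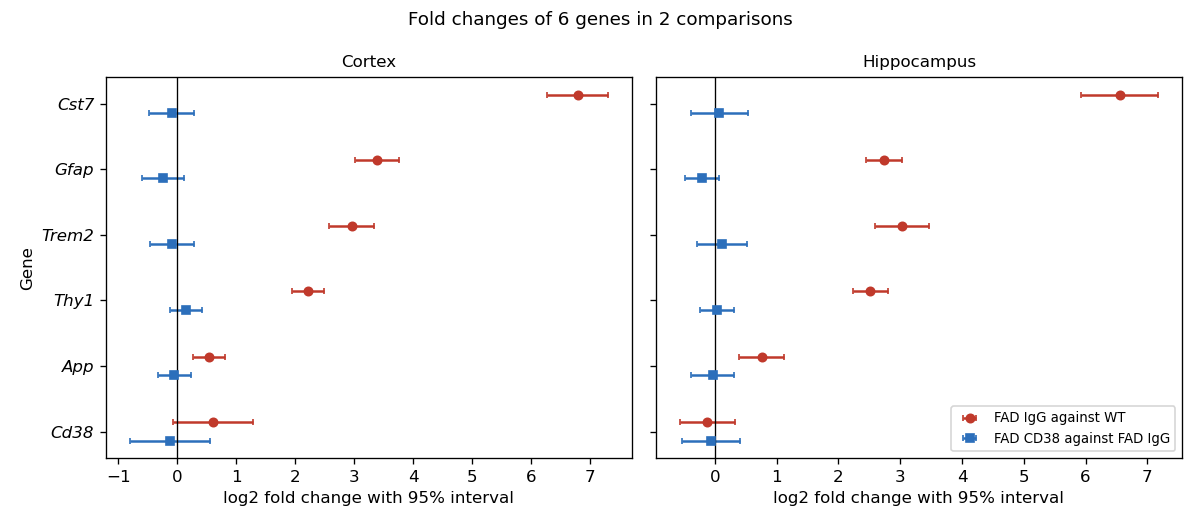
Points give the log2 fold change (x axis) with 95% intervals for Cst7, Gfap, Trem2, Thy1, App and Cd38 (y axis) in each region, for FAD IgG against WT (circles) and FAD CD38 against FAD IgG (squares). Cst7 stands at 6.79 and 6.55 for the first comparison and at -0.09 and 0.07 for the second.

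Whether genes changed in FAD mice moved back in the CD38 group was asked over the 502 called genes in cortex and the 623 in hippocampus. The CD38 change had the opposite sign to the FAD change for 72.5% and 65.8% of them. Both changes share the IgG mice, which alone gives opposite signs: in 50 simulations with the FAD effect and no CD38 effect the median share was 70.4% (67.4 to 74.7) in cortex, with 4 as high as observed, and 68.3% (64.7 to 71.4) in hippocampus, with 49 as high. Each simulation used the genes it called itself, a median of 1068 and 1043, so these sets are larger than the observed ones. With no effect of either kind, over the 502 and 623 genes, the median was 68.8% (63.7 to 74.5) and 67.8% (61.5 to 71.7), with 1 and 41 of 50 as high as observed. With the IgG mice split between the comparisons and the pool left out of the model it was 49.8% (25 to 70.8) and 51.1% (26.9 to 67.2) over 20 draws, with a median of 369 and 549 genes called. Over all tested genes, the same set in both, the observed share was 58% in cortex and 56% in hippocampus, below all 50 simulations with a FAD effect (median 61%, 60.4 to 62.1, and 60.3%, 58.9 to 61.2). The covariance of the changes over all tested genes was -0.0171 and -0.0163, against -0.0255 and -0.0289 in those simulations. All simulations drew each gene independently, so their ranges leave out genes that move together between mice. Over called genes the SD of the share was 1.47 and 1.51 with a FAD effect. Over the splits of the IgG mice, which also had fewer mice per group, it was 13.4 and 11.7. How many simulations were as high or lower therefore does not measure chance.

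The CD38 group was also set against WT, where it carried the glial signature of the IgG group. In cortex Cst7 rose by 6.70 ± 0.24 (SE, n = 7 and 9, adjusted p = 1.06e-14), Ccl6 by 3.79 ± 0.15 (adjusted p = 1.06e-14), Thy1 by 2.36 ± 0.13 (adjusted p = 4.72e-12), Gfap by 3.15 ± 0.17 (adjusted p = 8.58e-12) and Trem2 by 2.88 ± 0.18 (adjusted p = 1.05e-10). Apln (-1.13 ± 0.16, adjusted p = 4.02e-05), Npas4 (-1.49 ± 0.23, adjusted p = 0.000121), Btbd17 (-0.81), Kcnab1, a potassium channel subunit (-0.75), Acsbg1, a fatty acyl-CoA ligase (-0.58), and Nsmf (-0.53) fell. Cd38 did not pass (0.48, adjusted p = 0.451). In all 428 genes rose and 159 fell of 12968.

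In FAD CD38 cortex against WT, 31 of 34 disease-associated microglia genes rose (33 adjusted over the list alone), 16 of 23 interferon response genes (22 adjusted over the list alone), 15 of 21 reactive astrocyte genes (17, with 1 lower, adjusted over the list alone) and 7 of 7 MHC class II genes (7 adjusted over the list alone), with Cd74 at 2.54. Complement genes rose in 9 of 12 (11, with 1 lower, adjusted over the list alone), MHC class I genes in 8 of 12 (11), homeostatic microglia genes in 11 of 18 (13), lysosomal genes in 17 of 28 (17) and the IL-1 and IL-17 list in 4 of 14 (4, adjusted p = 0.0469 with an estimated correlation). The nuclear respiratory chain list had 14 of 75 members that fell (44 adjusted over the list alone, median -0.35, adjusted p = 0.181 with an estimated correlation), among them Ndufc2 (-0.41, lost without pool 8) and Ndufv2 (-0.46, lost without any 1 of pools 5, 6, 8, 9 and 11). Endothelial genes fell in 2 of 18 (4 adjusted over the list alone, median -0.24, adjusted p = 0.134 with an estimated correlation), Itm2a at -0.83 and the transporter gene Slco1a4 at -0.74 (lost without pool 6, 7 or 8). Striatal markers had a median of -0.73 with 0 called singly (8 adjusted over the list alone, adjusted p = 0.195 with an estimated correlation). Of 40 lists 11 were higher and 7 lower, and 11 kept their call with an estimated correlation.

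The count of changed genes in FAD CD38 cortex against WT moved with the samples and the tool. Without pool 6 it was 331 higher and 51 lower, and without pool 8 333 and 32. The number lower was also 44 without pool 5, 63 without pool 9, 293 without pool 10 and 48 without pool 11. DESeq2 split its calls into 457 and 314, voom with sample quality weights into 650 and 497, and a fit of only the 2 groups compared into 516 and 303. Among alternatives chosen after seeing the data, the ribosomal RNA share as a covariate gave 1286 and 804 and the mouse of conflicting labels counted as CD38 453 and 245.

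In hippocampus FAD CD38 mice differed from WT by a rise of Cst7 (6.62 ± 0.29, adjusted p = 2.76e-11; n = 7 and 8), Tyrobp (2.86 ± 0.13, adjusted p = 2.76e-11), Thy1 (2.56 ± 0.13, adjusted p = 1.52e-10), Gfap (2.53 ± 0.14, adjusted p = 1.64e-10) and C1qb (2.27 ± 0.12, adjusted p = 2.08e-10). Crhbp (-0.71, adjusted p = 0.000736), the somatostatin-related peptide gene Cort (-0.97, adjusted p = 0.0181, lost without pool 5, 7, 10 or 11), the nociceptin precursor gene Pnoc (-0.72, lost without pool 10), Spink8 (-0.88, lost with the mouse of conflicting labels counted as CD38) and Lin7b (-0.61) fell. In all 580 genes rose and 96 fell of 12728. Without pools 5 to 11 in turn the number that fell was 43, 28, 52, 287, 50, 19 and 28.

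In FAD CD38 hippocampus against WT, 33 of 34 disease-associated microglia genes (33 adjusted over the list alone), 19 of 23 interferon response genes (23 adjusted over the list alone), 19 of 23 reactive astrocyte genes (20 adjusted over the list alone), 12 of 13 complement genes (12 adjusted over the list alone) and 6 of 7 MHC class II genes (7 adjusted over the list alone) rose. Inhibitory neuron markers were lower as a list, with 1 of 17 falling (4 adjusted over the list alone, median -0.23, adjusted p = 0.00616 with an estimated correlation). Of 39 lists 14 were higher and 4 lower, and 12 kept their call with an estimated correlation. The hippocampus of FAD CD38 replicate 4 had a ribosomal RNA share of 17.2%. DESeq2 split its calls into 660 higher and 238 lower, voom with sample quality weights into 1553 and 1203, and a fit of only the 2 groups compared into 354 and 20, and without a filter on low counts they were 611 and 56. Among alternatives chosen after seeing the data, leaving out wells of high ribosomal RNA share gave 993 and 1006, the share as a covariate 1094 and 518 and the mouse of conflicting labels counted as CD38 650 and 147.

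**Figure D3:**
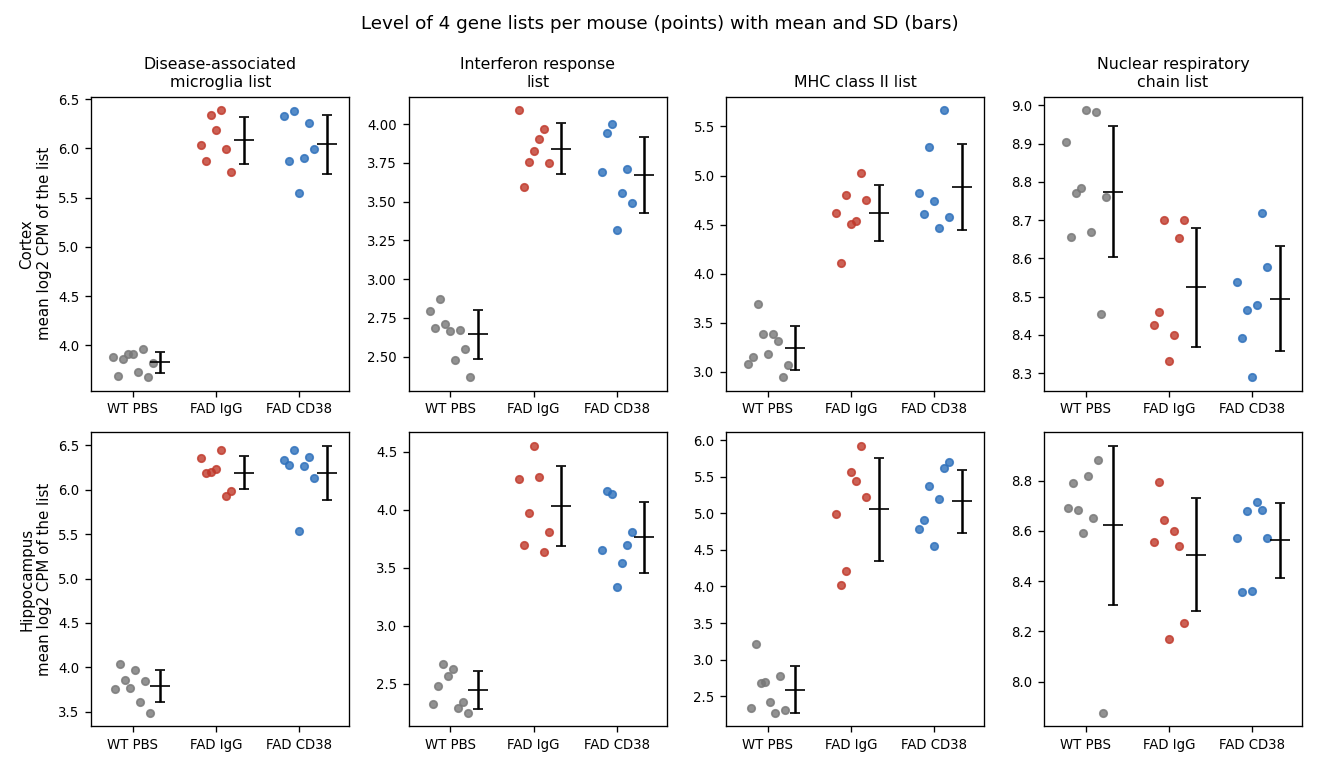
Each point is 1 mouse, with its mean log2 CPM over a gene list on the y axis, for WT PBS, FAD IgG and FAD CD38 mice on the x axis, and bars give the mean and SD. In cortex the disease-associated microglia level is 6.08 in FAD IgG against 3.83 in WT, and the FAD CD38 points overlap those of FAD IgG in all 4 lists drawn.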

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

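The tests of microglial share, chance between mice, neuron share, short transcripts and striatal tissue were chosen only after the results they bear on had been seen, and so was leaving out wells of high ribosomal RNA share from the levels. The ribosomal RNA share as a covariate was also chosen after seeing the data, though before its own result was known, and the splits of the mice were set beforehand. The number of splits was raised from 40 to 100 after the first 40 had been seen. In those 40, FAD CD38 against WT in cortex had 2 splits as large. The mean of both regions for FAD IgG against WT had 3. Over all 100 splits each had 3, and neither set of splits settles chance. The test of neuron share replaced a first version, the respiratory chain minus the neuronal level (two-sided exact permutation p = 0.0673), which had left the question open.

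Among 144 groups of mice and measures, 18 had a mouse far from the others, where chance gives about 1 in 20. The hippocampus of FAD CD38 replicate 4 accounts for 9: its ribosomal RNA share was 17.2% (next 7.336%), its disease-associated microglia level 5.54, its homeostatic microglia level 3.998 and its mitochondrially encoded level 8.912. In log2 CPM it had Thy1 at 9.024, Trem2 at 6.7, Cst7 at 6.33, Clec7a at 2.003 and Gfap at 7.927, each the lowest of its group. The hippocampus of WT replicate 9 had a ribosomal RNA share of 23.7% (next 5.57%), a mitochondrial share of 21.38% (next 11.11%), a mitochondrially encoded level of 10.37 and a nuclear respiratory chain level of 7.876 (next 8.59). FAD IgG hippocampus had replicate 6 at 4.384 for homeostatic microglia genes and replicate 4 at 4.509 for NAD metabolism genes. In FAD CD38 cortex, replicate 2 stood at 3.229 for the IL-1 and IL-17 list, replicate 7 at 11.26 for mitochondrially encoded genes and replicate 4 at 2.315 log2 CPM for Clec7a (next 3.891).

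For 6 lists the effect of FAD IgG against WT on the level per mouse differed between regions. The test was a two-sided exact permutation test of the hippocampus effect minus the cortex effect. Each level averaged the list members tested in its own region, so the genes compared were not always the same. The difference was 1.124 for MHC class II, 0.4276 for reactive astrocytes, 0.399 for the interferon response, 0.3676 for complement and 0.2719 for the IL-1 and IL-17 list, each with an adjusted p of 0.0112, and 0.4276 for MHC class I (adjusted p = 0.0252). Reactive astrocytes had 21 members in cortex and 23 in hippocampus, complement 12 and 13, and MHC class I 12 and 11. For these lists a stronger response in hippocampus cannot be told from a change of members. Whether the other lists kept the same members was not compared. Part of the difference lay in WT: complement in hippocampus minus cortex was -0.312 in WT and 0.0558 in FAD IgG. The WT value was below 0 for each of the 6 lists except MHC class I (0.0529). By limma voom 30 genes differed as well. The cause was not tested.

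The mouse of conflicting labels stood above the WT range. Its disease-associated microglia level was 5.986 in cortex (WT 3.692 to 3.967) and 6.123 in hippocampus (WT 3.511 to 4.015), and its interferon level 3.701 (WT 1.924 to 2.292) and 4.304 (WT 1.814 to 2.2), over list members tested across both regions together. The interferon levels were also above the highest FAD IgG mouse (3.608 and 4.095) and the highest FAD CD38 mouse (3.476 and 3.709), while the microglia levels lay within the range of both groups.

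The first pattern weighed is the lower interferon list in FAD CD38 than in FAD IgG mice in both regions. The tests of chance between mice go apart: the level per mouse over both regions differed by -0.2194 with a two-sided exact permutation p of 0.118, which leaves chance open, while the camera p of the list was as small in 3 of 100 splits of the mice in each region, fewer than 1 in 20, for a list picked out after its result was seen. Those splits were drawn without regard to pool. A lower share of microglia stays open: the disease-associated microglia level differed by -0.0208 (95% interval -0.311 to 0.2695, which includes the interferon difference), the homeostatic level by -0.1209 (-0.3617 to 0.1198), and the interferon minus the disease-associated level gave an exact p of 0.0857. In cortex 16 of 18 homeostatic and 25 of 34 disease-associated microglia genes were below 0, with 11 of 12 complement and 24 of 28 lysosomal genes. FAD CD38 replicate 4 was the lowest of its group in cortex and hippocampus for the disease-associated (5.549 and 5.54), homeostatic (4.068 and 3.998) and interferon levels (3.317 and 3.336). In cortex and hippocampus 5 and 5 of 7 FAD CD38 mice had an interferon level below the FAD IgG mean. For the homeostatic level these were 5 and 3, and for the disease-associated level 4 and 2. The lower interferon level thus did not rest on that mouse alone. Differences without it were not tested. With the ribosomal RNA share in the model the difference was -0.224 (95% interval -0.463 to 0.0158), so RNA quality cannot be told apart either, the interval including 0 before and after. An effect of the CD38 treatment is the biological explanation the design names, and it was not separated from these.

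The second pattern is the lower nuclear respiratory chain level in FAD IgG than in WT cortex (-0.2498, two-sided exact permutation p = 0.0108). RNA quality is argued against as the whole cause only as far as the ribosomal RNA share measures it, and that share includes mitochondrial ribosomal RNA. With the share in the model the difference went from -0.2498 (95% interval -0.4147 to -0.0849) to -0.255 (-0.421 to -0.0882). Without wells of high share, however, it was -0.1932 (-0.3907 to 0.0043, 5 and 8 mice) and no longer passed the exact permutation test (adjusted p = 0.0737). A lower share of neurons is argued against only as far as the excitatory neuron and synaptic vesicle lists cover it, whose mean level differed by 0.0553 (95% interval -0.0933 to 0.204). Inhibitory neuron markers were not part of that test, and 12 of 18 of them were below 0 (camera adjusted p = 0.0713 with the preset correlation). A loss of short abundant transcripts cannot be told apart, since the respiratory chain minus the ribosomal protein level gave an exact p of 0.0506, and the ribosomal protein level alone differed by 0.0088 (95% interval -0.2949 to 0.3126, which includes the respiratory chain difference). A lower expression in FAD cortex stays open as a hypothesis, confounded with the injection.

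The third pattern is the lower level of striatal markers in FAD IgG than in WT cortex (-0.8058, two-sided exact permutation p = 0.00481), with a range of 3.35 to 5.22 in FAD IgG, 3.51 to 5.17 in FAD CD38 and 4.5 to 5.37 in WT. Striatal tissue carried into some cortex samples is a candidate explanation. After removing group and pool the markers moved together between mice, with a mean pairwise correlation of 0.736 across mice against a highest of 0.345 in 10000 random lists. Markers of 1 tissue can move together by shared regulation too, so this does not separate the 2. Camera's estimated correlation in cortex was 0.74 for these markers, 0.563 for nuclear respiratory chain genes and 0.552 for mitochondrially encoded genes. RNA quality is argued against as the whole cause, since the difference with the ribosomal RNA share in the model was -0.789 (95% interval -1.34 to -0.242). A difference of striatal genes within cortex stays open and untested.

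Other splits of the same mice were drawn 100 times for each comparison of groups, and for hippocampus against cortex the regions were flipped within mice. The splits took mice freely across pools, while the real groups had mostly 1 mouse per pool. They therefore differ from the real grouping in their balance over pools and cannot settle whether chance made its counts. Few splits had as many called genes as the real groups of FAD and WT mice. For FAD IgG against WT this held in cortex (502; 2 splits as large, the real one included; highest other 825) and hippocampus (623; 1; 138). For FAD CD38 against WT it held in cortex (587; 3; 1413) and hippocampus (676; 1; 235). It also held for FAD IgG against WT over the mean of both regions (983; 3; 3702) and the difference between regions (30; 1; 1). These small numbers do not exclude chance, since the splits differ in their balance over pools. For hippocampus against cortex, whose flips stayed within mice, chance can be excluded (5808; 1; 0). The count at an unadjusted p under 0.05 was as large in more splits, except for hippocampus against cortex (1). For FAD IgG against WT these were 6 in cortex and 4 in hippocampus, and for FAD CD38 against WT 4 and 5. The mean of both regions had 10 and the difference between regions 7. For the mean of both regions 3 of the first 40 splits had as many called genes. The split with 3702 genes, several times the real count, points to a structure of the samples. Its difference in ribosomal RNA share between the sides of the split (log2 scale) was 0.5419, as large in 7 of 100 splits, against 0.0963 for the split with 1413 genes, as large in 72, and 0.303 for that with 825, as large in 32.

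For FAD CD38 against FAD IgG 0 genes were called by edgeR and limma voom, so all 100 splits are as large by construction and their number says nothing about chance (highest other 2 in cortex, 0 in hippocampus, 2033 for the mean of both regions and 128 for the difference between regions). By the count at an unadjusted p under 0.05, 90 of 100 splits were as large in cortex (195 genes), 85 in hippocampus (197), 81 for the mean of both regions (233) and 100 for the difference between regions (289), so chance cannot be excluded. The split with 2033 genes had a ribosomal RNA difference of 0.5803, as large in 2 of 100, and also points to a structure of the samples.

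For the number of lists called by camera with the preset correlation chance cannot be excluded between FAD CD38 and FAD IgG. Against WT the splits cannot decide it. A split with unequal numbers of FAD mice on its sides keeps part of the genotype difference. Single lists were tested by exact permutation of levels per mouse instead. For FAD IgG against WT in cortex the disease-associated microglia level passed (adjusted p = 0.000131) and the glycolysis level did not (0.43). FAD IgG against WT gave 19 lists in cortex, with 21 splits as large (highest other 23), and 21 in hippocampus, with 11 (25). FAD CD38 against FAD IgG gave 17, with 12 (21), and 9, with 44 (20). FAD CD38 against WT gave 18, with 22 (24), and 18, with 20 (23).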

How the results depend on the processing

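The settings of ribosomal RNA share, of the mouse with conflicting labels and of WT replicate 9 were chosen after seeing the data, and the others beforehand. The values below are numbers of called genes, higher and lower together, unless named as lists. With voom and sample quality weights FAD IgG against WT went from 502 to 806 in cortex, from 623 to 1928 in hippocampus and from 983 to 2060 over the mean of both regions, FAD CD38 against WT from 587 to 1147 and from 676 to 2756, and the difference between regions from 30 to 473. DESeq2 gave 609 and 783 for FAD IgG against WT and 771 and 898 for FAD CD38 against WT. With the ribosomal RNA share as a covariate FAD IgG against WT gave 1152 and 1118, and FAD CD38 against WT 2090 and 1612. Leaving out wells of high share gave, in hippocampus, 1121 and 1999, and 11 for the difference between regions. Only the 2 groups compared gave 374 for FAD CD38 against WT in hippocampus. The cause was not tested for any of these. FAD CD38 against FAD IgG gave 0 genes by edgeR, DESeq2 and voom in every alternative, with 123 to 559 at an unadjusted p under 0.05 in cortex and 158 to 1057 in hippocampus. Evenly spread p-values would give 648.4 and 636.4 in the main fits, so the low number in hippocampus did not hold in every alternative. Other splits of the mice gave medians of 456 and 359 in the main fits, and the highest alternative lay above them in both regions.

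Lists called with an estimated correlation were 11 and 12 for FAD IgG against WT (18 and 17 with fry), 0 and 0 for FAD CD38 against FAD IgG (0 and 0 with fry) and 11 and 12 for FAD CD38 against WT (14 and 14 with fry). With the pool left out of the model FAD CD38 against FAD IgG in cortex had 11 lists. The nuclear respiratory chain list of FAD CD38 against FAD IgG in hippocampus reversed to lower without the wells of high ribosomal RNA share (adjusted p = 0.0122, over alternatives 2.9e-11 to 0.948), and the cause was not tested. Without those wells the NAD metabolism level of FAD IgG against WT in cortex also turned, from 0.09 to -0.0037 (adjusted p = 0.932, over alternatives 0.0154 to 0.932), and its cause was not tested either.

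With each pool left out in turn FAD IgG against WT gave 368 to 671 genes in cortex and 435 to 787 in hippocampus, and FAD CD38 against WT 365 to 728, with 382 without pool 6 and 365 without pool 8, and 459 to 958. Lists ran from 7 to 19 for FAD CD38 against FAD IgG in cortex and 6 to 13 in hippocampus. The share of opposite signs was 49.8% and 51.1% with the FAD IgG mice split between the comparisons and the pool left out of the model. Over all tested genes it was 58% in cortex, where simulations with no CD38 effect gave 61% (60.4 to 62.1). Those simulations drew each gene independently, so that range is too narrow for a test. Without the replicate block of the mouse, hippocampus against cortex had 5038 genes in place of 5808.

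Of 240 alternative counts 211 stayed within 1.5 times the main one and 29 did not. Of 9159 values of named genes 8686 kept direction and side of the threshold, 164 lost and 309 gained a call. Of 1530 single list values 1313 did so, 216 lost the call and 1 reversed, and of 240 list levels 228 did, 3 lost and 8 gained a call and 1 reversed. Sex as a covariate was not run, since every well held Xist, nor were both changes of the depth minimum, which would have moved no well. PBS against IgG within a genotype was not analysed here. In single regions, changes of 1.5-fold between groups were mostly out of reach for single genes at this depth. Over the mean of both regions 58.2% were recovered for FAD CD38 against FAD IgG, in simulated log2 values with the same noise in every well.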

Other observations

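Ctsd and Gm49369 were named after their values were seen, and the levels without WT replicate 9 or without wells of high ribosomal RNA share were chosen after seeing the data. In hippocampus of FAD IgG mice Gpx1, a glutathione peroxidase, rose by 0.63 and Ftl1, a ferritin light chain gene, by 0.69 on the log2 scale (adjusted p = 0.00854, lost without pool 5, and 0.0156, lost without pool 5, without pool 10 and in a fit of only the 2 groups compared). Apod, a lipocalin of myelinating glia, rose by 0.72 in cortex and 1.08 in hippocampus (adjusted p = 0.00041 and 0.0022), and Cldn11, a tight junction gene of myelin, by 0.91 in cortex. Slc1a3, the astrocyte glutamate transporter, rose by 0.47 in hippocampus (adjusted p = 0.0392, lost in 6 alternatives), and Fibcd1, a marker of hippocampal pyramidal cells, fell by 0.44 (adjusted p = 0.0329, lost in 7).

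Levels per mouse add a view in which each mouse counts once. By two-sided exact permutation tests adjusted over 12 lists, mitochondrially encoded genes were lower in FAD IgG than in WT by -0.42 in cortex (adjusted p = 0.0128) and -0.22 in hippocampus (adjusted p = 0.0363, which became 0.0978 after removing the pool). Nuclear respiratory chain genes were lower by -0.25 in cortex (adjusted p = 0.013, which became 0.0737 without wells of high ribosomal RNA share). In hippocampus they were lower in 6 of 6 pools (-0.65 to -0.038) but did not pass (-0.12, adjusted p = 0.434), and without WT replicate 9, whose level of 7.876 lay far below the others, the difference was -0.20 (adjusted p = 0.0381). NAD metabolism genes were higher by 0.09 in cortex (adjusted p = 0.0439), a difference of -0.0037 without wells of high ribosomal RNA share (adjusted p = 0.932). In hippocampus they did not pass (0.05, adjusted p = 0.24) and did without WT replicate 9 (0.10, adjusted p = 0.0315). That setting kept FAD IgG replicate 4, also a well of high share, which stood highest of its group for this list at 4.509 (next 4.393). The difference between the regions' effects did not pass for these 3 lists (adjusted p = 0.26, 0.335 and 0.519 by exact permutation tests). In the CD38 group against WT the nuclear respiratory chain level was lower by -0.28 in cortex (adjusted p = 0.00595) and the mitochondrially encoded level by -0.35 (adjusted p = 0.0263), and the NAD metabolism level was higher by 0.10 (adjusted p = 0.0251, which became 0.5 without wells of high ribosomal RNA share). In hippocampus the mitochondrially encoded level did not pass (-0.36, adjusted p = 0.0569), and passed after removing the pool (adjusted p = 0.034), without WT replicate 9 (0.00622) and without wells of high ribosomal RNA share (0.00155). Much of the size of -0.36 comes from FAD CD38 replicate 4, a well of high share, at 8.912. The others of its group lay at 10.46 to 10.68, against a WT mean of 10.72. The nuclear respiratory chain level there (-0.06, adjusted p = 0.714) passed without wells of high share (-0.16, adjusted p = 0.0161), and the NAD metabolism level (0.07, adjusted p = 0.137) without WT replicate 9 (0.11, adjusted p = 0.0252). Between FAD CD38 and FAD IgG none of the 12 levels passed in either region. MHC class I in hippocampus was the 1 level of a single sign in all 6 pools that held both groups (lower by -0.70 to -0.023), with a difference over all mice of -0.14 (adjusted p = 0.922), which was 0.0018 without wells of high ribosomal RNA share (adjusted p = 0.996).

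A gene of the cathepsin family shares its locus with a longer annotated gene. Ctsd stood at 1.75 CPM in WT cortex while the overlapping Gm49369 stood at 477, and both were higher in FAD IgG cortex (log2 fold changes 2.55 and 2.11). How counts were divided between them is not given in the sources used here.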
